A study of Homo sapiens with 24 samples.

How the data were processed

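Total RNA from the human breast cancer line BT474, labelled with biotin and hybridised to Illumina bead arrays, was measured on 24 arrays. The labels give a drug naive and a drug resistant form of the line, each sampled at 0, 10 and 20 h of 1 µM lapatinib, with 4 arrays in each of the 6 groups. Lapatinib is an inhibitor of the ERBB2 and EGFR kinases, and BT474 is a luminal line with amplified ERBB2. The labels hold no untreated arrays at 10 or 20 h, and they do not say whether the replicates were separate cultures or whether the resistant cells were kept in drug before 0 h. The p-values therefore measure the spread between these samples, which may in part be technical.

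The authors read the arrays with GenomeStudio, per the submitters' processing notes, which give no version. The deposited table of probe signals holds a mean bead intensity on a linear scale for 47321 probes, not normalized between arrays. Beside each intensity the authors deposited a detection p-value, the share of negative control probes at or above that signal. A separate deposited table holds the authors' normalized log2 values for 22013 of the probes. Its normalization and probe filter are not given in the sources used here. Its columns followed the unnormalized intensities of the same arrays, with 24 of 24 columns matching their own array best, and their medians lay between 5.45 and 5.47, so that the arrays had been brought to a common centre. That table was used only as an alternative.

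The intensities were background corrected with the normexp method, with the background taken from the detection p-values, an offset of 16 was added, and the arrays were quantile normalized on the log2 scale (the neqc function of limma 3.58.1 in R 4.3.3). A probe entered when its detection p-value was under 0.05 on at least 4 of the 24 arrays, which left 23451 probes. Of all probes, 15197 had 1 gene symbol in the platform annotation, 0 had several, and 32124 are unnamed here. Of the named probes, 15185 matched a current gene record by gene number and 5 by transcript accession alone, and 3 symbols were updated in all. The 12469 entering probes with a name gave 12210 genes, each represented by its probe with the highest mean intensity. Of these genes 255 had more than 1 entering probe. Among the 90 genes taken by the rule for named genes given below, only NOP16 had a further entering probe with a name, which changed in the same direction. The other genes in the report were not checked in this way, and 10982 entering probes had no name here.

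A linear model with a mean for each group was fitted to all 24 arrays with limma (lmFit and eBayes, without trend), and genes were called at a Benjamini-Hochberg adjusted p-value under 0.05 over the 12210 genes. The comparisons were resistant against naive cells at each time, 10 h and 20 h against 0 h in each form of the line, and the difference between these responses (an interaction term) at each time. Fold changes are differences of mean log2 intensity and SE is the standard error of the fit, with 4 arrays in each group. A probe above background on none of the 4 arrays of a group has only a bound there. Its fold is given as at least the ratio of the brighter group to the higher of the probe's own signal and the lowest signal called present on each array of the dimmer group.

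Before the data were examined, 30 gene lists were fixed from general knowledge, covering signalling output, cell cycle, metabolism, stress, lineage and markers of other cell types. The 28 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison. Camera with an estimated correlation and fry were run beside it. The rule for named genes was fixed at the same time. For each of 4 comparisons (resistant against naive at 0 h, each response at 20 h, and their difference at 20 h) it takes the 6 genes that rose most and the 6 that fell most among called genes. These need 4 replicate values that do not overlap between the groups (except for the difference) and a signal above background on all 4 arrays of the brighter group (of any group, for the difference). It adds the 2 called members of each called list with the largest change in the list's direction. It always takes ERBB2, EGFR, ERBB3, ESR1, CCND1, DUSP6, MKI67 and IRS2. The genes named at 20 h are also followed at 10 h. Other members of a list named below illustrate its count and were chosen after their values were seen.

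The arrays fell into 2 sets that the labels do not name. Replicates 1 and 2 had 15081 to 16794 probes above background and a 95th percentile of signal 6.99 to 9.97 times the median. Replicates 3 and 4 had 19166 to 21486 such probes and a ratio of 12.7 to 19.4. The first principal component of the deviations from the group means held 38.9% of their variance and placed 24 of 24 arrays on the side of their set. Arrays with the same replicate number deviated together, with a mean correlation across genes of 0.343, against 0.340 for the other number of the same set and -0.339 between sets. Every same-numbered pair in every comparison had a correlation over 0.1 (lowest 0.127), so the numbers were taken as pairing the arrays, through the set rather than through each number. The pairing comes from the data, since the labels give the numbers without saying what they mark. Each set holds every group equally. The fit without a block stayed the main one, as fixed beforehand, and values with the replicate number as a block, or within each set, are given beside it. The estimated correlation of list genes was taken only from the fit without a block, so variation between the sets enters it. Whether list calls lost with that correlation would stand with one estimated under a block was not tested.

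Median signals ranged from 65.2 to 87.4 over the arrays, no arrays had identical values, and correlations between arrays lay between 0.888 and 0.993. With 4 arrays per group, the number of arrays limits the precision. On simulated data with the spread of these genes and 12210 genes, the 20 h response of naive cells was recovered for 100% of genes changed by 2 on the log2 scale, for 59.7% of those changed by 1 and for 1.49% of those changed by 0.5. For the difference of responses at 20 h these shares were 81.8%, 28.4% and 1.49%. Only 66 genes were changed by 2, 67 by 1 and 67 by 0.5, whereas 2380 genes were called in the real 20 h response of naive cells. The adjusted threshold loosens as more genes change, so these shares do not give the recovery in the real comparisons. In a further simulation of the same kind, a list moved by 0.5 in naive cells at 20 h was called and 0 of the 27 others were. The simulated genes varied independently and without the sets of arrays described above. False calls of lists whose genes vary together were therefore not tested.

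The alternatives were quantile normalization without background correction, scaling to the 75th percentile, an offset of 50, the authors' normalized values, no filter, a stricter filter (detection p-value under 0.01 on all arrays of a group), the mean of a gene's probes, each probe on its own, eBayes with trend and robust, array weights, only the groups compared, the replicate number as a block, the same block within each form of the line, and leaving out each array. A block for the chip was planned and not run, since the columns used here name no chip. Settings chosen after seeing the data were the set as a block, each set alone, and the median of the ribosomal protein genes of each array as a covariate. That median differed between the groups, so as a covariate it also takes away any part of a group difference that moves with it. Figures were drawn with matplotlib.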

Results

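The expression of 12210 genes was compared between drug naive and drug resistant BT474 breast cancer cells at 0, 10 and 20 h of 1 µM lapatinib, with 4 arrays in each of 6 groups. Changes are on the log2 scale, where 1 unit is a 2-fold change, with the standard error (SE) of the limma fit and its adjusted p. Between 15081 and 21486 probes per array were above background, fewer in replicates 1 and 2 than in replicates 3 and 4. The probe named for ERBB2 was above background on only a few arrays of any group, and those for MKI67 and EGFR on 2 of the 4 arrays in each group, so these probes say little about the levels of their transcripts.

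The comparison at 0 h asked how the resistant cells differed from the naive ones before the timed exposure. Resistant cells had more SCGB2A2 (mammaglobin, a secreted protein of breast epithelium) by 3.65 ± 0.35 (SE, adjusted p = 3e-07), more of the kallikrein protease KLK11 by 2.71 ± 0.34, of ornithine aminotransferase OAT by 2.68 ± 0.19 and of the adhesion molecule CEACAM1 by 2.47 ± 0.18. The fatty acid receptor CD36 and the transcription factor TBX1 were not above background in naive cells and were at least 3.46-fold and 3.25-fold higher in resistant cells (adjusted p = 3.08e-09 and 1.72e-06). The chemokine CXCL14 was lower by -3.39 ± 0.26, the inflammasome adaptor PYCARD by -2.70 ± 0.27, the intermediate filament gene VIM by -2.26 ± 0.29, the metallothionein MT2A by -2.11 ± 0.46 and the synaptic adhesion gene NLGN4X by -1.93 ± 0.26. The lipid carrier APOE, not above background in resistant cells, was at least 2.16-fold lower there. In resistant cells at 0 h, VIM and CXCL14 were above background on 2 of 4 arrays and NLGN4X on 1.

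Among the lists at 0 h, mesenchymal markers were lower in resistant cells, with 3 of the 8 measured genes called lower (3 when adjusted over the list alone) and adjusted p = 0.000435 by camera. These were VIM, the cadherin CDH2 (-1.39 ± 0.26, above background on 2 of 4 resistant arrays) and TWIST1 (-1.14), and the call held with an estimated correlation (adjusted p = 0.00929). Interferon response genes were higher, with 4 of 21 called (5 higher and 1 lower adjusted over the list alone). MX1 was higher by 1.96 ± 0.29 and ISG15 by 1.71 ± 0.43, with 2.90 for ISG15 in replicates 1 and 2 and 0.52 in replicates 3 and 4, and ISG15 was above background on 2 of 4 naive arrays and MX1 on 3. The list test gave adjusted p = 0.0103, but adjusted p = 0.0854 with an estimated correlation and 0.064 with array weights. In the ERK pathway output list 3 of 19 genes were higher (5 adjusted over the list alone), namely the phosphatase DUSP5 (1.41 ± 0.17), the feedback inhibitor SPRY1 (1.04 ± 0.20) and cyclin D1, CCND1 (0.71 ± 0.19). That call (adjusted p = 0.0267) was lost with the replicate block (adjusted p = 0.0676), with an estimated correlation (adjusted p = 0.288) and on only the groups compared (adjusted p = 0.0666). It was also lost on replicates 1 and 2 alone, and with the ribosomal protein median of each array as a covariate, a setting chosen after seeing the data. CCND1, ISG15 and MT2A lost their calls when only the groups compared were fitted (adjusted p = 0.0594, 0.0503 and 0.0599).

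Further lists passed camera at 0 h with few or no single genes. The ATF4 and amino acid response list was higher (1 of 30 genes called and 4 adjusted over the list alone, adjusted p = 0.000827), with asparagine synthetase ASNS up by 0.96 ± 0.22. NRF2 targets were higher (1 of 12 and 3, adjusted p = 0.0313), with the quinone reductase NQO1 up by 0.68 ± 0.19, and glycolysis genes were higher (0 of 18 and 1, adjusted p = 0.0335). Oxidative phosphorylation genes were lower (0 of 32 and 0, median -0.25, adjusted p = 0.000435). That call ended with the ribosomal protein covariate (median 0.00662, adjusted p = 0.941). The 72 ribosomal protein genes had a median of -0.53 at 0 h. With an estimated correlation these 4 lists gave adjusted p = 0.288, 0.477, 0.544 and 0.288. The NRF2 and glycolysis calls, with that of NQO1, also ended with 75th percentile scaling (adjusted p = 0.184, 0.43 and 0.167), and fry did not call these 2 lists or oxidative phosphorylation. The BCL2 family list was lower, with 1 of 16 genes called, the survival gene BCL2 (-1.58 ± 0.25, adjusted p = 0.000271), and 3 adjusted over the list alone. The autophagy and lysosome list was higher with 0 of 21 genes called by either count. These last 2 list calls, each at adjusted p = 0.0459, were lost with the replicate block (adjusted p = 0.0942 and 0.0691) and with an estimated correlation (adjusted p = 0.288 and 0.477). They were also lost with 75th percentile scaling, only the groups compared, the set as a block, the covariate, fry and replicates 1 and 2 alone. ERBB3 (-0.33 ± 0.16), ESR1 (-0.47 ± 0.24), DUSP6 (0.56 ± 0.27) and the insulin receptor substrate IRS2 (-0.04 ± 0.24) did not pass the test, nor did the probes of EGFR (-0.06 ± 0.35), MKI67 (0.08 ± 0.31) and ERBB2 (-0.24 ± 0.27). With array weights ERBB3 and DUSP6 did pass (adjusted p = 0.0173 and 0.0237).

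In all, 307 genes differed at 0 h, 175 higher and 132 lower in resistant cells, 161 of them by at least 2-fold. With the replicate number as a block the count was 733, including all 307, and within replicates 1 and 2 and within replicates 3 and 4 it was 99 and 147. Leaving out replicate 1 of resistant cells at 0 h gave 185, array weights gave 2096 and the ribosomal protein covariate 113.

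At 10 h of lapatinib 804 genes differed between the forms of the line (422 higher and 382 lower in resistant cells), and at 20 h 1322 (617 higher and 705 lower). These counts lie above the 307 at 0 h, but array weights turned that order, with 2096, 960 and 1566 genes at 0, 10 and 20 h. SCGB2A2 was higher by 4.46 ± 0.35 and 4.52 ± 0.35 and OAT by 2.93 ± 0.19 and 2.98 ± 0.19. VIM was lower by -2.51 ± 0.29 and -2.92 ± 0.29, and BCL2 by -1.30 ± 0.25 and -1.95 ± 0.25. FOXO targets, which at 0 h had 0 genes higher and 1 lower of 18, had 9 lower at 10 h and 10 lower at 20 h (12 at each time adjusted over the list alone), with camera adjusted p = 1.86e-09 and 1.13e-09 and with an estimated correlation adjusted p = 0.00462 and 0.00411. Ribosome biogenesis genes were higher in resistant cells, 10 of 20 at 10 h and 8 at 20 h, with adjusted p = 0.0143 and 0.0419 with an estimated correlation. At 20 h 6 interferon response genes were higher and 1 lower (adjusted p = 0.0419 with an estimated correlation). Other lists passed camera at 20 h at the preset correlation alone, among them cholesterol synthesis (7 of 19 higher, adjusted p = 0.0622 with an estimated correlation) and drug efflux and detoxification (5 of 9 lower, adjusted p = 0.13 with an estimated correlation). The counts with the replicate block were 1501 and 2232, and with only the groups compared 428 and 796. Without replicate 2 of naive cells at 10 h the first was 524. Within replicates 1 and 2 they were 185 and 419, and within replicates 3 and 4 they were 797 and 1253.

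**Figure D1:**
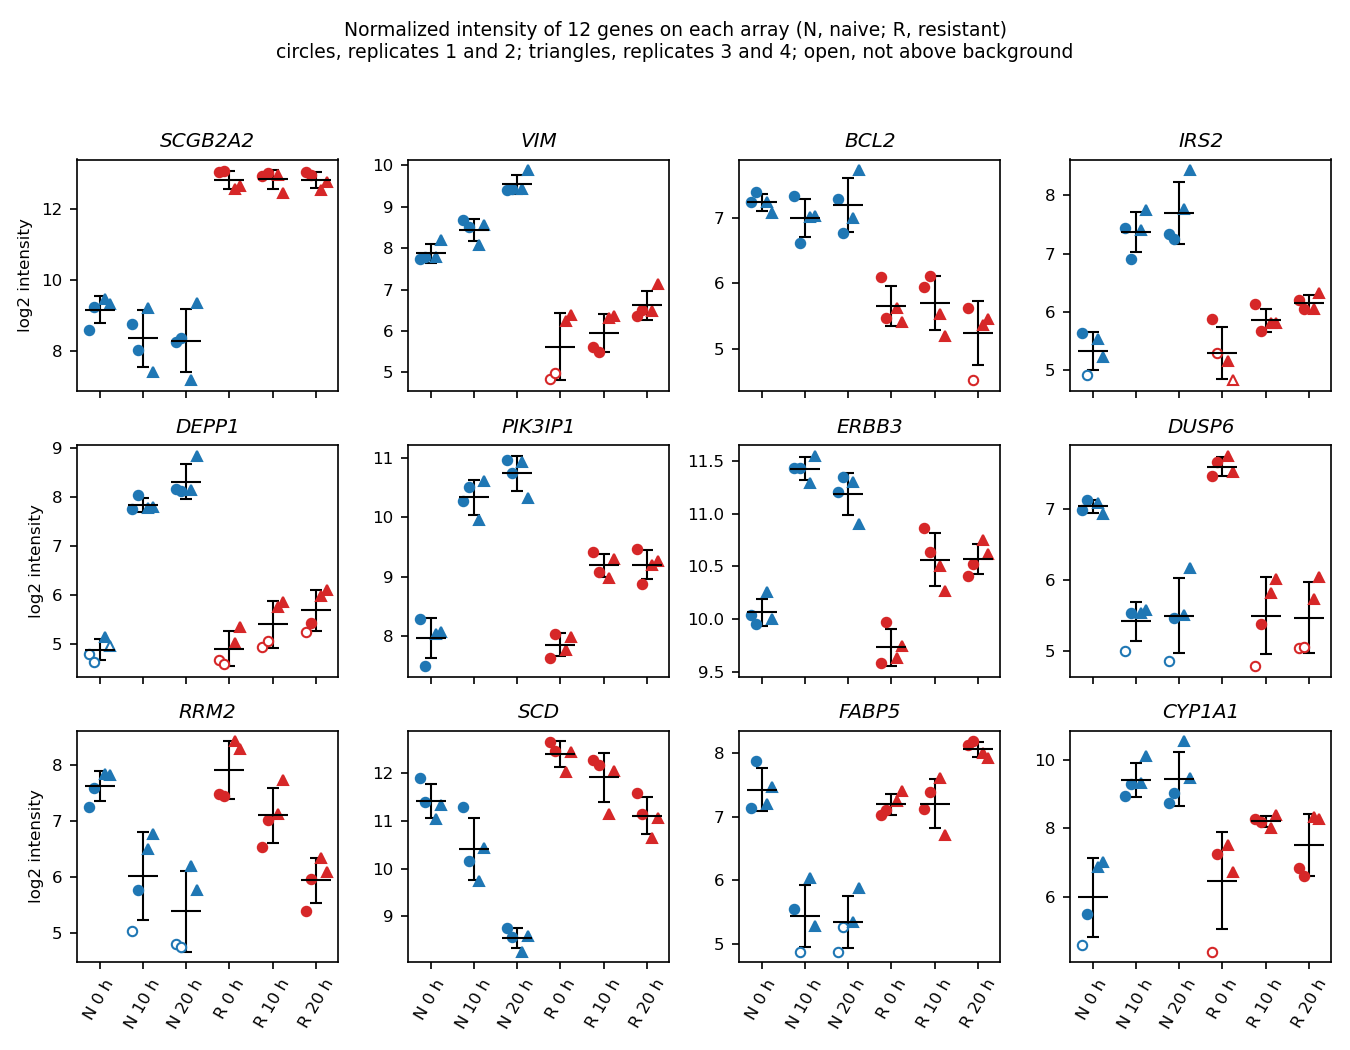
Normalized log2 intensity (y axis) of 12 genes in the 6 groups (x axis), with a point for each of 24 arrays and black bars for the mean and SD of 4 arrays. SCGB2A2 lay between means of 12.8 and 9.17 in resistant and naive cells at 0 h, and DEPP1 rose by 3.43 in naive cells by 20 h.

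The response of naive cells to lapatinib was the broadest change. By 20 h the FOXO target DEPP1 had risen by 3.43 ± 0.24 (adjusted p = 7.26e-10), the xenobiotic-metabolising enzyme CYP1A1 by 3.45 ± 0.57, PGM5 (a phosphoglucomutase-related protein of cell adhesions) by 3.40 ± 0.17, IQCN by 3.09 ± 0.31, the pregnancy glycoprotein PSG4 by 2.99 ± 0.24 and the oxidised LDL receptor OLR1 by 2.97 ± 0.29. The stearoyl-CoA desaturase SCD fell by 2.86 ± 0.28 (adjusted p = 1.34e-07), and lower were the ERK phosphatase DUSP4 (-2.38 ± 0.29) and the neuronal gene BRINP2 (-2.32 ± 0.36). The ribosomal protein genes RPS24 (-2.50 ± 0.38), RPL29 (-2.41 ± 0.31) and RPS7 (-2.31 ± 0.33) fell. RPL29, RPS7 and DUSP4 were above background on 2 of 4 arrays at 20 h and BRINP2 on 3. At 0 h DEPP1 was above background on 1 of 4 arrays, OLR1 on 2, and CYP1A1 and IQCN on 3. At 20 h RPL29 and RPS7 had means of 5.12 and 5.35, close to background, so their falls rest in part on it. The 3 ribosomal protein genes were taken for their large falls, whereas the median change of the 72 measured was -0.46. The median of this family varied between arrays of 1 group, as described in the closing section.

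Of 18 measured FOXO targets, 14 rose and 0 fell at 20 h in naive cells (15 rose adjusted over the list alone). The phosphoinositide 3-kinase inhibitor PIK3IP1 rose by 2.77 ± 0.20, IRS2 by 2.36 ± 0.24, FOXO1 by 1.84 ± 0.24 (above background on 3 and 2 of 4 arrays at 0 h) and the receptor ERBB3 by 1.13 ± 0.16. The list had a median of 1.04, with 1.21 in replicates 1 and 2 and 1.11 in replicates 3 and 4, and camera gave adjusted p = 4.97e-15 and with an estimated correlation adjusted p = 0.000375. Of 35 genes of DNA replication and the G1/S transition 26 fell and 0 rose (29 adjusted over the list alone), among them the ribonucleotide reductase subunit RRM2 (-2.24 ± 0.36) and the phosphatase CDC25A (-2.08 ± 0.33), each above background on 2 of 4 arrays at 20 h. Their median was -0.89, with -0.94 and -0.92 in the sets, and adjusted p = 0.00206 with an estimated correlation. Mitosis genes did not pass the list test, with 1 of 34 higher and 5 lower. In ribosome biogenesis 14 of 20 genes fell (14 adjusted over the list alone), with NOP16 at -1.52 ± 0.18 and BOP1 at -1.29 ± 0.24, a median of -0.78 (-0.95 and -0.70 in the sets) and adjusted p = 0.0071 with an estimated correlation.

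Transcripts of lipid synthesis genes fell in naive cells. Of 19 cholesterol synthesis genes 12 fell and 1 rose (12 and 3 adjusted over the list alone), with ACAT2 at -1.96 ± 0.25 and the sterol reductase DHCR7 at -1.96 ± 0.21, and SC5D rose by 0.74. Of 11 fatty acid synthesis genes 7 fell (7 adjusted over the list alone), with SCD and the desaturase FADS2 (-1.77 ± 0.25) in front. The medians were -0.83 and -0.99, and with an estimated correlation adjusted p = 0.0105 and 0.0306. Glycolysis genes (5 of 18 lower and 7 adjusted over the list alone) included lactate dehydrogenase LDHA at -1.05 ± 0.22 and PGAM1 at -0.87 ± 0.23. Oxidative phosphorylation genes (9 of 32 and 15) included the ATP synthase subunit ATP5MC1 at -1.93 ± 0.27 and COX7B at -1.36 ± 0.43. Estrogen receptor targets (7 of 22 lower and 2 higher, 9 and 2 adjusted over the list alone) included the receptor kinase RET at -2.20 ± 0.23 and TFF1 at -2.13 ± 0.41. Heat shock genes (4 of 11 lower and 6 adjusted over the list alone) included HSP90AA1 at -1.10 ± 0.37 (above background on 2 of 4 arrays at 20 h) and HSPH1 at -0.96 ± 0.22. These 4 lists passed camera (adjusted p = 0.00187, 3.63e-06, 0.00234 and 0.0115), and with an estimated correlation gave adjusted p = 0.174, 0.108, 0.16 and 0.16.

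Lists that rose in naive cells at 20 h besides the FOXO targets passed camera at the preset correlation, and each gave adjusted p = 0.16 with an estimated correlation. In drug efflux and detoxification 5 of 9 genes rose (5 adjusted over the list alone), with CYP1A1 and the transporter ABCC5 (2.00 ± 0.20) in front (camera adjusted p = 0.00107). In autophagy and lysosome 6 of 21 rose and 2 fell (7 and 2 adjusted over the list alone), with GABARAPL1 at 2.02 ± 0.22 and the lysosomal glycoprotein GPNMB at 1.85 ± 0.22 (adjusted p = 0.00645). Of 9 basal epithelial markers 3 rose (3 adjusted over the list alone), with the adhesion receptor CD44 at 1.31 ± 0.29 and caveolin CAV1 at 1.19 ± 0.25 (adjusted p = 0.0296, and 0.0959 with array weights). The ERK pathway output list did not pass, and of its 19 genes 6 fell and 2 rose. DUSP6 fell by 1.54 ± 0.27 (above background on 3 of 4 arrays at 20 h), CCND1 by 0.67 ± 0.19 and the adaptor SPRED1 by 1.44. The ephrin receptor EPHA4 rose by 1.57 ± 0.21 and MYC by 1.09. Of the markers of other cell types, 0 of 5 leukocyte markers rose and CORO1A fell by 1.63 (above background on 1 of 4 arrays at 20 h), and the fibroblast and endothelial lists, with 4 and 3 measured genes, were too small to test. ESR1 (-0.21 ± 0.24), ERBB2 (0.00 ± 0.27) and MKI67 (-0.09 ± 0.31) did not pass the test. EGFR, at 0.57 ± 0.35, did not pass either, but did with the replicate block (adjusted p = 0.00469), with 75th percentile scaling (adjusted p = 0.0321) and on replicates 3 and 4 alone (adjusted p = 0.0134).

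In naive cells 2380 genes were called at 20 h, 1309 higher and 1071 lower, 913 of them by at least 2-fold. Within replicates 1 and 2 and within replicates 3 and 4 the counts were 1144 and 2105, and with each probe on its own, where more features are tested, 3652. Scaling to the 75th percentile gave 1058 higher and 1364 lower, so the balance of rises and falls rests on the quantile normalization.

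At 10 h, 1801 genes were called in naive cells, 932 higher and 869 lower. CYP1A1 had risen by 3.42 ± 0.57, IQCN by 3.08 ± 0.31, DEPP1 by 2.95 ± 0.24, PIK3IP1 by 2.37 ± 0.20, IRS2 by 2.04 ± 0.24 and ERBB3 by 1.37 ± 0.16. DUSP6 had fallen by 1.62 ± 0.27, DUSP4 by 1.91 ± 0.29, CCND1 by 0.94 ± 0.19, RRM2 by 1.61 ± 0.36 and SCD by 1.00 ± 0.28. FOXO targets had 14 of 18 genes higher, ribosome biogenesis 14 of 20 lower with a median of -1.13, and DNA replication 7 of 35 lower, with adjusted p = 0.000334, 0.000573 and 0.0743 with an estimated correlation. The count with the replicate block was 2749, and within the sets 701 and 1326. Scaling to the 75th percentile gave 633 higher and 1105 lower.

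The response of resistant cells at 20 h was led by the cerebellin gene CBLN2, up by 2.24 ± 0.27 (adjusted p = 3.52e-05), the glucuronosyltransferase UGT1A6 by 1.90 ± 0.37, GPNMB by 1.76 ± 0.22, the histone gene H2AC6 by 1.67 ± 0.24, the selenium carrier SELENOP by 1.65 ± 0.21 and IGFBP3, a binding protein of insulin-like growth factors, by 1.56 ± 0.21. DUSP6 fell by 2.13 ± 0.27, RRM2 by 1.96 ± 0.36, CDC25A by 1.87 ± 0.33, DUSP4 by 1.77 ± 0.29, the methylation maintenance factor UHRF1 by 1.77 ± 0.18 and TENT5C by 1.76 ± 0.25.

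The ERK pathway output list fell in resistant cells, with 6 of 19 genes lower and 0 higher (7 lower adjusted over the list alone). Besides DUSP6 and DUSP4 these were SPRED1 (-1.57, above background on 2 of 4 arrays at 20 h), SPRED2 (-1.17), CCND1 (-1.02 ± 0.19) and ETV5, which was not above background at 20 h. DUSP6 and CDC25A were above background on 2 of 4 arrays at 20 h. The median was -0.42, with -0.36 and -0.51 in the sets, and adjusted p = 0.00259 with an estimated correlation. DNA replication and G1/S genes fell, 19 of 35 (27 adjusted over the list alone), with a median of -0.87 (-0.78 and -0.92 in the sets) and adjusted p = 8.36e-05 with an estimated correlation. Of 18 FOXO targets 5 rose (9 adjusted over the list alone), namely PIK3IP1 (1.35 ± 0.20), GABARAPL1 (1.31 ± 0.22), CCNG2 (0.98), RBL2 (0.96) and ERBB3 (0.84 ± 0.16), with a median of 0.54 (0.50 and 0.48 in the sets) and adjusted p = 0.00259 with an estimated correlation. Cholesterol synthesis (4 of 19 lower, 8 lower and 1 higher adjusted over the list alone) and fatty acid synthesis (4 of 11, 6 adjusted over the list alone) fell, each with adjusted p = 0.0214 with an estimated correlation. MVD was at -1.25 ± 0.26, DHCR7 at -1.13 ± 0.21, SCD at -1.28 ± 0.28 and FADS2 at -1.20 ± 0.25.

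Other lists passed camera in resistant cells at 20 h at the preset correlation and not with an estimated one. Lower were the ATF4 and amino acid response (4 of 30 genes and 10 lower adjusted over the list alone), with the transporter SLC7A5 at -1.04 ± 0.22 and the pseudokinase TRIB3 at -0.90 ± 0.23, mitosis (2 of 34 by either count, PRC1 at -0.69 ± 0.16 and AURKB at -0.66 ± 0.18), glycolysis (1 of 18, ALDOA at -0.73 ± 0.18) and ribosome biogenesis (2 of 20, nucleolin NCL at -0.83 ± 0.19 and PPAN at -0.64 ± 0.17). With an estimated correlation these gave adjusted p = 0.0853, 0.114, 0.254 and 0.131. Other receptor tyrosine kinases were lower (2 of 10 lower and 1 higher, RET at -1.62 ± 0.23, FGFR3 at -0.73 ± 0.18 and MERTK at 0.86, adjusted p = 0.131 with an estimated correlation). That call was also lost with array weights, 75th percentile scaling, no filter, the set as a block, the replicate block within line, only the groups compared, the covariate and either set alone. Autophagy and lysosome genes were higher (4 of 21, GPNMB and GABARAPL1 in front, adjusted p = 0.185 with an estimated correlation). IRS2, at 0.87 ± 0.24, did not pass, but did with the replicate block (adjusted p = 0.0159), with array weights (1.17, adjusted p = 7.24e-06), with the stricter filter (adjusted p = 0.0322) and on replicates 3 and 4 alone (adjusted p = 0.0406). ESR1 (0.52 ± 0.24), EGFR (0.09 ± 0.35), ERBB2 (0.06 ± 0.27) and MKI67 (-0.04 ± 0.31) did not pass, though ESR1 did with array weights (adjusted p = 0.0156).

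In resistant cells 381 genes were called at 20 h, 174 higher and 207 lower, 153 of them by at least 2-fold. The count was 909 with the replicate block, 72 and 137 within the sets, and 238 without replicate 4 of resistant cells at 20 h. Array weights gave 1875, against 2561 in naive cells, so the size of the gap between the 2 counts at 20 h depends on how the arrays are weighted. The ribosomal protein covariate gave 183 and ended the calls of CCND1, SCD, FADS2, DHCR7 and MVD, among others. Scaling to the 75th percentile gave 113 higher and 235 lower. At 10 h 132 genes were called, 71 higher and 61 lower, with DUSP6 at -2.10 ± 0.27, CCND1 at -1.05 ± 0.19, CBLN2 at 1.79 ± 0.27 and PIK3IP1 at 1.34 ± 0.20. RRM2 (-0.81 ± 0.36), UHRF1 (-0.57 ± 0.18) and SCD (-0.48 ± 0.28) did not pass at 10 h, though RRM2 did with the replicate block (adjusted p = 0.024). The 10 h count was 373 with the replicate block, 687 with array weights, 42 with only the groups compared and only 3 and 22 within the sets. It was 67 without replicate 2 of resistant cells at 10 h, and scaling to the 75th percentile gave 39 higher and 53 lower.

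**Figure D2:**
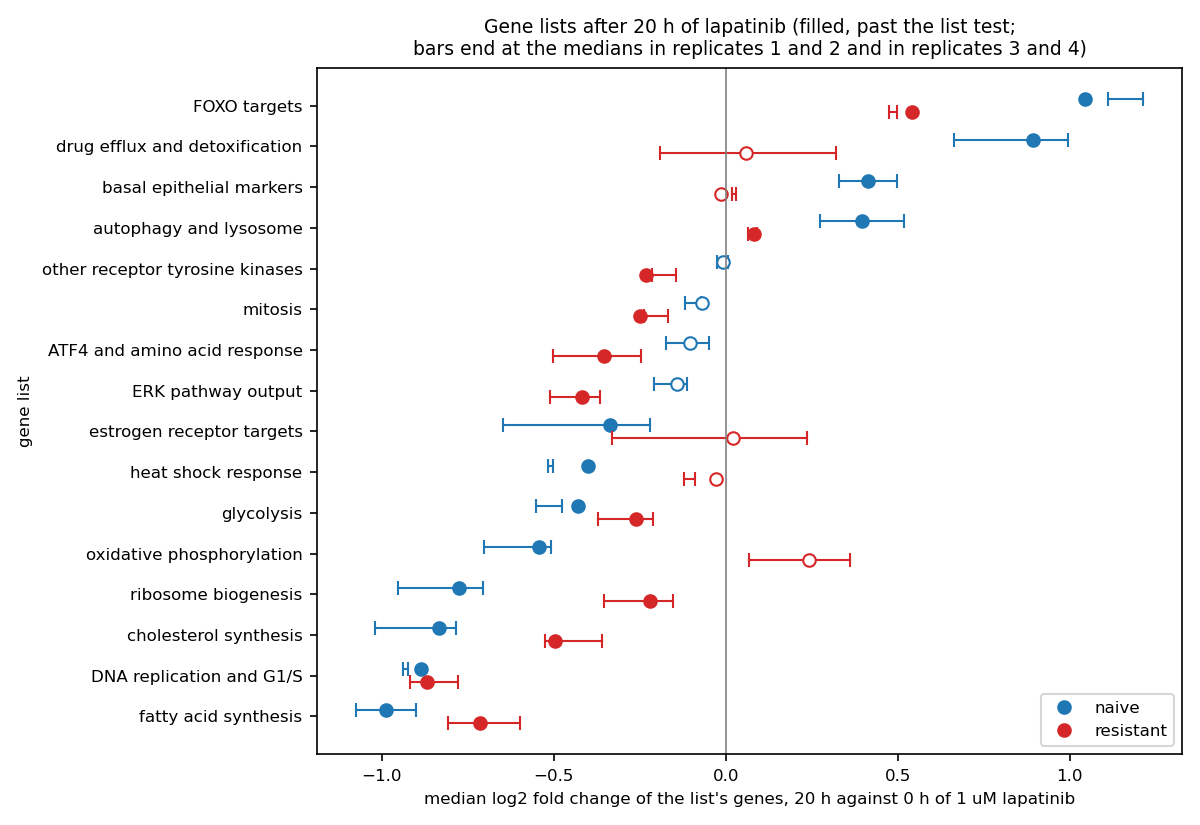
Median log2 fold change (x axis) of the genes of each list (y axis) at 20 h against 0 h in naive and resistant cells, filled where the list passed camera, with bars that end at the medians in replicates 1 and 2 and in replicates 3 and 4. FOXO targets lay at 1.04 in naive and 0.54 in resistant cells, and DNA replication genes at -0.89 and -0.87.

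The interaction term asked which responses differed between the forms of the line. At 20 h the fatty acid binding protein FABP5 fell by 2.08 ± 0.24 in naive cells and rose by 0.87 ± 0.24 in resistant cells, a difference of 2.95 ± 0.34 (adjusted p = 2.02e-05). The secreted mucin-like gene MUCL1 fell by 2.12 in naive cells and moved by 0.07 ± 0.23 in resistant cells (difference 2.19 ± 0.32). For the calcium-binding protein S100A4 the difference was 2.34 ± 0.55, for ATP5MC1 2.21 ± 0.38, for RPS24 2.38 ± 0.53 and for RPL29 2.17 ± 0.44. In the other direction, PSG4 (difference -2.68 ± 0.33), DEPP1 (-2.64 ± 0.34), the iron reductase CYBRD1 (-2.54 ± 0.28), IQCN (-2.49 ± 0.44), the matrix protein TGFBI (-2.38 ± 0.38) and the potassium channel KCNJ13 (-2.29 ± 0.41) rose in naive cells, by between 2.43 (TGFBI) and 3.43 (DEPP1). They did not pass the test in resistant cells, though DEPP1 did with the replicate block (adjusted p = 0.00691). CYBRD1 was above background on 1 of 4 arrays at 0 h in each form and on 0 of 4 in resistant cells at 20 h, so its difference rests in part on background and is not an exact value. KCNJ13 was above background on 2 of 4 arrays at 0 h in each form, and FABP5 and RPL29 on 2 of 4 in naive cells at 20 h.

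Of 18 FOXO targets 5 had a lower change in resistant than in naive cells and 0 a higher one (6 and 0 adjusted over the list alone), among them DEPP1, FOXO1 (-1.56 ± 0.34) and IRS2 (-1.50 ± 0.35). The median difference was -0.59, with -0.64 and -0.59 in the sets, and adjusted p = 0.0101 with an estimated correlation. The DNA replication list, with a median difference of 0.02, had 0 of 35 genes with a called difference and did not pass. Ribosome biogenesis (3 of 20 higher and 4 adjusted over the list alone, NOP16 at 1.31 ± 0.26 and WDR12 at 0.97 ± 0.24), oxidative phosphorylation (2 of 32 and 13, ATP5MC1 and ATP5PO at 1.55 ± 0.38), cholesterol synthesis (1 of 19 and 2, EBP at 1.18 ± 0.30) and estrogen receptor targets (0 of 22 and 3) had positive differences. In resistant cells these lists had medians of -0.22, 0.24, -0.50 and 0.02, of which only cholesterol synthesis passed as lower with an estimated correlation (adjusted p = 0.0214). With an estimated correlation the differences gave adjusted p = 0.0775, 0.0578, 0.19 and 0.304. The oxidative phosphorylation median difference of 0.66 was 0.21 with the ribosomal protein covariate, chosen after seeing the data (camera adjusted p = 0.00442). The lower start of that list in resistant cells at 0 h also enters its difference. With array weights the cholesterol synthesis and estrogen receptor calls ended (adjusted p = 0.144 and 0.174). Drug efflux and detoxification genes (2 of 9 lower and 3 adjusted over the list alone, ABCC3 at -1.83 ± 0.41 and ALDH1A3 at -1.53 ± 0.38, above background on 1 to 3 of 4 arrays in each group), basal epithelial markers (0 of 9 and 2) and ERK pathway output (1 of 19 and 1, EPHA4 at -1.58 ± 0.29) had negative differences, with adjusted p = 0.19, 0.19 and 0.261 with an estimated correlation. The ERK call also ended with 75th percentile scaling (adjusted p = 0.0516), as did the called difference of IRS2 (adjusted p = 0.0959). Within the ERK pathway output list the difference did not pass for DUSP6 (-0.59 ± 0.37) or CCND1 (-0.35 ± 0.27). ERBB3 (-0.28 ± 0.22), ESR1 (0.73 ± 0.34), EGFR (-0.48 ± 0.49), MKI67 (0.04 ± 0.43) and ERBB2 (0.05 ± 0.38) did not pass either. DUSP6 had means of 7.03 in naive and 7.59 in resistant cells at 0 h, and of 5.49 and 5.46 at 20 h. At 20 h it was close to background in both forms, so its difference lies mainly in the 0 h levels.

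The difference was called for 236 genes at 20 h (108 higher and 128 lower in resistant cells) and for 22 at 10 h (7 higher and 15 lower), DEPP1 (-2.46 ± 0.34), CYBRD1 (-2.13 ± 0.28) and FABP5 (1.99 ± 0.34) among the latter. The replicate block gave 802 and 72, while the sets alone gave 15 and 10 at 20 h and 2 and 0 at 10 h, where 4 groups of 2 arrays remain and the limma count at an unadjusted p under 0.05 over all arrays was 1086. Leaving out replicate 2 of naive cells at 0 h gave 102 at 20 h and 7 at 10 h. In the same order an offset of 50 gave 399 and 40, the stricter filter 389 and 40 and array weights 724 and 59. At 10 h scaling to the 75th percentile gave 10 and only the groups compared 8. With the ribosomal protein median of each array as a covariate, a setting chosen after seeing the data, 13 genes were called at 20 h and 6 at 10 h, and FOXO1 and IRS2 were no longer called. The FOXO targets kept a median difference of -0.46 at 20 h (camera adjusted p = 1.19e-07). The covariate itself differed between the groups, with a ribosomal protein median difference of responses of 0.72 at 20 h. This fit therefore also takes away any part of the group differences that moves with the covariate, so the lost calls are not shown to be false.

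Across the 12210 genes, which are not independent replicates, the responses of naive and resistant cells at 20 h had a Pearson correlation of 0.411 and a Spearman correlation of 0.346, and at 10 h of 0.547 and 0.460. These responses share no arrays. The Pearson correlation at 20 h was 0.255 within replicates 1 and 2 and 0.513 within replicates 3 and 4, and at 10 h it was 0.368 and 0.590. Of the genes called at 20 h in naive cells (2380) and in resistant cells (381), 116 rose in both and 126 fell in both, where independent lists would share 18.7 and 18.2, and 3 changed in opposite directions.

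**Figure D3:**
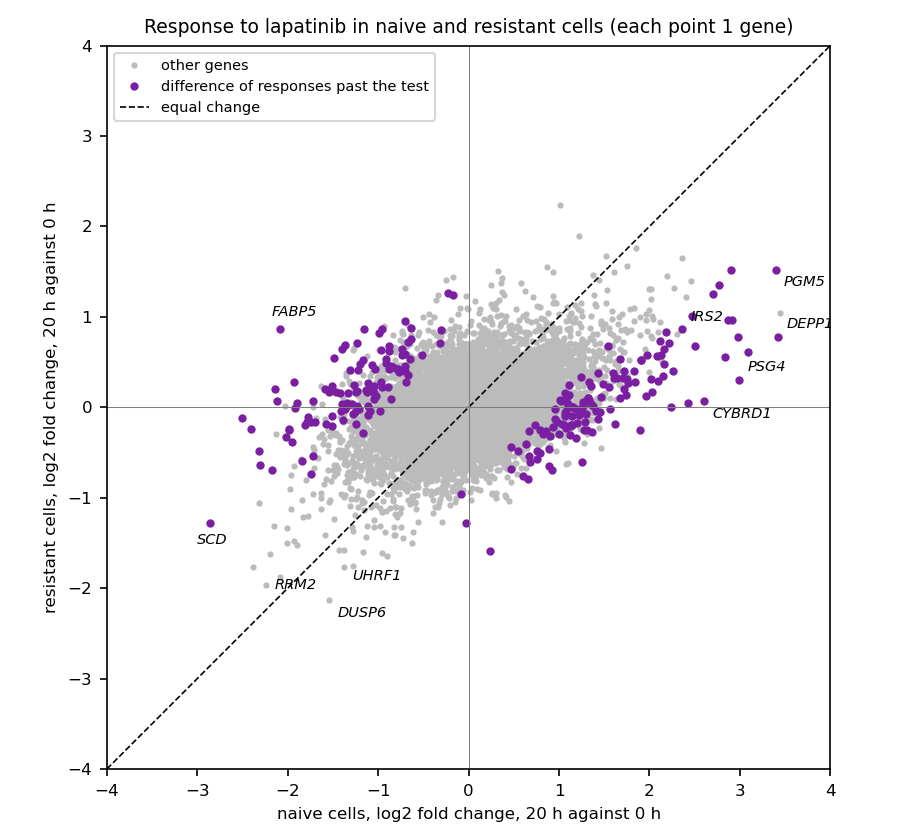
Log2 fold change at 20 h against 0 h in resistant cells (y axis) against naive cells (x axis), with a point for each of 12210 genes and the 236 genes with a called difference of responses in purple. The Pearson correlation was 0.411, and the points at the far right, such as DEPP1 and PSG4, lie below the dashed line of equal change.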

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

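Of the tests in this part, those of a like compression of all genes, of the FOXO list within each set, of genes chosen by resistant cells, of the ribosomal protein covariate on the FOXO and oxidative phosphorylation lists, of the CYP1A1 paralogs and of untreated arrays were chosen after the results were seen.

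The difference of responses at 20 h was past the test for 27 of the 90 named genes. Resistant cells had the lower change for CEACAM1 (-1.25), IRS2 (-1.50), DEPP1 (-2.64), PGM5 (-1.87), IQCN (-2.49), PSG4 (-2.68), OLR1 (-2.19), PIK3IP1 (-1.42), CYBRD1 (-2.54), TGFBI (-2.38), KCNJ13 (-2.29), EPHA4 (-1.58), FOXO1 (-1.56), ABCC3 (-1.83) and ALDH1A3 (-1.53). They had the higher change for SCD (1.58), RPS24 (2.38), RPL29 (2.17), RPS7 (1.83), ATP5MC1 (2.21), NOP16 (1.31), FABP5 (2.95), S100A4 (2.34), MUCL1 (2.19), EBP (1.18), ATP5PO (1.55) and WDR12 (0.97). CYBRD1 in resistant cells at 20 h and OLR1 in resistant cells at 0 h were not above background on any array, so their differences are not exact values. It was past the test for 8 lists, with median differences of -0.59 for FOXO targets, -0.35 for ERK pathway output, -0.48 for basal epithelial markers, -0.69 for drug efflux and detoxification, 0.50 for cholesterol synthesis and for ribosome biogenesis, 0.66 for oxidative phosphorylation and 0.30 for estrogen receptor targets. With a correlation estimated on the fit without a block, only the FOXO targets passed (adjusted p = 0.0101), and the call was lost for the other 7.

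At 20 h FOXO targets rose less in resistant than in naive cells, and the SD of the fold changes of all 12210 genes was 0.357 in resistant and 0.562 in naive cells. A compression of every gene alike on the resistant arrays is argued against by the DNA replication list, whose median in resistant cells was 0.978 times that in naive cells (0.889 to 1.09 when each array of the 0 h and 20 h groups was left out), while that of FOXO targets was 0.519 (0.453 to 0.538). A choice of genes that were large in naive cells by chance is argued against by the 1144 genes called on replicates 1 and 2, since on replicates 3 and 4 the resistant change was a median of 0.391 of the naive one, and 0.234 with the sets exchanged (2105 genes), while for 72 and 137 genes chosen by resistant cells in the same ways the naive change was a median of 1.05 and 1.01 of the resistant one (0.808 where the 381 genes were chosen and measured on the same arrays). An origin in a single set is argued against by the FOXO difference of -0.64 in replicates 1 and 2 and -0.59 in replicates 3 and 4, and with the ribosomal protein covariate it was -0.46, though only 13 single genes stayed called. A smaller FOXO response in the resistant form of the line may be the biological explanation, as a hypothesis found and tested on the same arrays, and whether an earlier exposure of the resistant cells to drug lowered it was not tested.

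Oxidative phosphorylation genes were lower in naive cells at 20 h and had a positive difference of responses at the preset correlation, and both calls were lost with an estimated one (adjusted p = 0.108 and 0.0578). The lowest median difference over the 4 other normalizations was 0.598, without background correction, and the value here was 0.664. Of the 4, only scaling to the 75th percentile is known to replace the quantile step between arrays, and it gave 0.866. That argues against the quantile step as the source, while further ways of scaling between arrays were not tested. An axis that varies between arrays of 1 group and is shared with the 72 measured ribosomal protein genes may account for most of the difference. Within groups the list mean moved by 0.702 for each unit of the ribosomal protein median of the array, and with that median as a covariate the difference was 0.210 (0.061 to 0.306 when each array was left out), though camera still gave adjusted p = 0.00442. RNA quality and a true shared change of these families remain open, and the biological difference between the forms of the line was not tested apart from them.

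CYP1A1 and CYP1A2 (chosen after its values were seen) rose in naive cells at 10 h by 3.42 ± 0.57 and 3.41 ± 0.42, and in resistant cells at 10 h CYP1A2 rose by 2.59 ± 0.42 and CYP1A1 was at 1.74 ± 0.57 (adjusted p = 0.179, and 0.0168 with the replicate block). Of the 4 other measured targets of the aryl hydrocarbon receptor, 1 was called higher in naive cells at 10 h, CYP1B1 (1.24 ± 0.37), and 2 at 20 h, TIPARP (0.55 ± 0.15) and UGT1A6 (1.22 ± 0.37), with 3 at each time with the replicate block. CYP1A2 was above background on 17 of 24 arrays, and a probe that binds both paralogs cannot be told apart from a true rise of each, since rises of other targets do not forbid it. An effect of medium or time in culture cannot be told apart from one of lapatinib, since 0 untreated arrays at 10 h or 20 h exist in the design. A response of the receptor to lapatinib may be a further explanation, as a hypothesis.

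Other splits of the arrays compared were counted for each comparison, 35 splits with the real one included. For resistant against naive cells at 0, 10 and 20 h the real splits gave 307, 804 and 1322 genes and the highest of the others 16, 1 and 7. For naive cells at 10 and 20 h they gave 1801 and 2380 against 1 and 6, and for resistant cells at 20 h 381 against 11. The differences of responses, split over the 8 series of arrays with the replicate block within line, gave 50 against 1 at 10 h and 717 against 0 at 20 h. In each of these 8 comparisons only 1 split, the real one, gave as many genes. For resistant cells at 10 h 2 of the 35 splits gave as many genes. The other one follows the sets, replicates 1 and 2 against 3 and 4, and called 653 genes against 132, which points to the structure of the arrays. The real split gave 373 with the replicate block and 3 and 22 within the sets, and of the 8 splits that part every replicate number the others called at most 0 genes in every comparison. These counts exclude chance in no comparison. The lowest share that can be reached is 1 of 35, or 1 of the 8 splits that part every replicate number. A split that mixes the groups also leaves the real difference in its residual spread, which lowers its count.

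Far values within a group of 4 arrays were sought in 268 groups, where chance would give about 13.4, and 10 were found. Against the mean of the other 3 arrays, CD36 in resistant cells at 0 h lay at -0.28 in replicate 3, CDC25A in naive cells at 0 h at 0.33 in replicate 4, DEPP1 in naive cells at 20 h at 0.70 in replicate 4 and GABARAPL1 in the same group at -0.87 in replicate 1. IQCN in naive cells at 0 h lay at -0.80 in replicate 2, KLK11 there at -0.72 in replicate 3 and VIM there at 0.44 in replicate 4. NOP16 in resistant cells at 20 h lay at 0.18 in replicate 2, TGFBI there at -0.79 in replicate 1 and PYCARD in resistant cells at 0 h at 0.30 in replicate 2.

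Among the 10982 entering probes without a name here, tested with the named ones, 124 differed between resistant and naive cells at 0 h, 1367 changed in naive cells at 20 h and 151 in resistant cells at 20 h.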

How the results depend on the processing

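Settings using the set, each set alone and the ribosomal protein median were chosen after seeing the data. Across eBayes with trend and robust, the mean of a gene's probes, no filter, the authors' values and no background correction, the 9 counts stayed within 1.5 times. The values that moved further are given by setting, and the cause was not tested. Scaling to the 75th percentile gave 10 for the difference at 10 h. An offset of 50 gave 40 and 399 for the differences at 10 and 20 h, and the stricter filter 40 and 389. Each probe on its own, with more features tested, gave 3652 for naive cells at 20 h. Array weights gave 2096 for resistant against naive at 0 h, 687 and 1875 for resistant cells at 10 and 20 h, and 59 and 724 for the differences. Only the groups compared gave 428 and 796 for resistant against naive at 10 and 20 h, 42 for resistant cells at 10 h and 8 for the difference at 10 h.

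The replicate block gave 733, 1501 and 2232 for resistant against naive at 0, 10 and 20 h, 2749 for naive cells at 10 h, 373 and 909 for resistant cells at 10 and 20 h, and 72 and 802 for the differences. The replicate block within line gave 2793, 334, 847, 50 and 717 for these last 5. The set as a block gave 753, 1524, 2272, 2774, 381, 937, 80 and 831 in the order of the replicate block. Among 131 tests of named genes in the 4 main comparisons the block ended 0 calls and added 2 (EGFR in naive and IRS2 in resistant cells at 20 h). Among 103 tests at 10 h it ended 0 and added 11, namely HSP90AA1 in naive cells, RRM2, CDC25A, UGT1A6, RET and NCL in resistant cells, and ATP5MC1, TGFBI, KCNJ13, WDR12 and IRS2 in the difference. Of 112 list tests in the 4 main comparisons, the block ended 3 calls, given in the report, and added 1. An estimated correlation (from the fit without a block) ended 28 and added 0, fry ended 7 and added 11, and 75th percentile scaling 6 and 3. Array weights ended 6 and added 6, only the groups compared 4 and 2, the stricter filter 3 and 1, the set as a block 3 and 0, the block within line 1 and 1, each probe on its own 1 and 2 and no filter 1 and 0. Replicates 1 and 2 alone ended 13 and added 2, replicates 3 and 4 alone 4 and 3, and the covariate ended 6, reversed 1 and added 4. Array weights ended interferon response and BCL2 family at 0 h, basal markers in naive and other receptor kinases in resistant cells, and cholesterol synthesis and estrogen receptor targets in the difference. Replicates 1 and 2 alone ended the ERK, glycolysis, ATF4, NRF2, BCL2 family and autophagy calls at 0 h and the estrogen receptor and basal ones in naive cells. They also ended the glycolysis, other receptor kinase and ribosome biogenesis ones in resistant cells, and the ERK and basal ones in the difference.

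Replicates 1 and 2 alone gave 99, 185 and 419 for resistant against naive, 701 and 1144 for naive cells, 3 and 72 for resistant cells, and 2 and 15 for the differences. Replicates 3 and 4 alone gave 147 for resistant against naive at 0 h, 22 and 137 for resistant cells, and 0 and 10 for the differences. The ribosomal protein covariate gave 113 for resistant against naive at 0 h, 183 for resistant cells at 20 h, and 6 and 13 for the differences. With it, 38 of 131 tests of named genes lost their call, and the oxidative phosphorylation median at 0 h turned from -0.25 to 0.00662 (adjusted p = 0.941). The correlation of responses at 10 h was 0.368 in replicates 1 and 2 alone.

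Leaving out 1 array gave 185 to 248 for resistant against naive at 0 h, 524 to 771 at 10 h and 925 to 1252 at 20 h, 1211 to 1900 and 1760 to 2282 for naive cells, 67 to 107 and 238 to 364 for resistant cells, and 6 to 35 and 102 to 358 for the differences at 10 and 20 h. Each of the 16 arrays moved the difference at 10 h by over 1.5 times. At 20 h the difference was 102 and 130 without naive 0 h replicates 2 and 4, 117 and 122 without resistant 0 h replicates 1 and 2, 143, 133 and 358 without naive 20 h replicates 1, 3 and 4, and 122 and 113 without resistant 20 h replicates 2 and 4. At 0 h the count was 190 and 199 without naive replicates 2 and 4 and 185 without resistant replicate 1. Resistant cells at 20 h gave 244, 252 and 238 without resistant 0 h replicate 1 and 20 h replicates 2 and 4. At 10 h they gave 76, 84 and 69 without 0 h replicates 1, 2 and 4, and 76 and 67 without 10 h replicates 1 and 2. Resistant against naive at 10 h gave 524 without naive replicate 2. Over all of these arrays, 109 tests of named genes lost their call and 0 reversed. List tests lost 36 calls and gained 28, most often losing ERK pathway output and basal markers in the difference and autophagy and BCL2 family at 0 h.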

Other observations

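Families outside the fixed lists were looked at after their values were seen, so the counts below describe these arrays. Of 38 measured histone genes of the replication-dependent clusters and linker histones, 10 rose and 0 fell in naive cells at 10 h, and 7 rose and 0 fell at 20 h. In resistant cells 2 rose and 0 fell at 10 h, and 6 rose and 0 fell at 20 h. Resistant cells had 8 lower and 0 higher at 0 h. H2BC5 rose by 1.53 ± 0.23 and 1.38 ± 0.23 in naive cells at 10 and 20 h and by 1.46 ± 0.23 in resistant cells at 20 h, and H3C10 rose by 1.75 ± 0.25, 1.70 ± 0.25 and 1.03 ± 0.25. H4C8 was lower in resistant cells at 0 h by -1.61 ± 0.25 and H2AC6 by -1.42 ± 0.24. The family median at 20 h was 0.45 in naive and 0.38 in resistant cells, and kept its sign under each of the 4 other normalizations and in each set. Its size was less stable, with 0.25 and 0.20 without background correction, 0.25 and 0.22 with an offset of 50, and 0.18 and 0.17 in replicates 3 and 4. The difference of responses at 20 h was called for 0 histone genes in the limma fit, and with the replicate block H2BC12 passed (0.89 ± 0.36, adjusted p = 0.0435). The DNA replication list fell in both forms of the line at the same time. Of 5 metallothionein genes, 2 were lower in resistant cells at 0 h, MT1F by -1.75 ± 0.36 and MT2A by -2.11 ± 0.46.

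The 72 ribosomal protein genes had 17 lower and 0 higher in naive cells at 20 h, with a median of -0.46, and 1 higher and 0 lower in resistant cells, with a median of 0.15. At 0 h they had 3 lower and 0 higher in resistant against naive cells, with a median of -0.53, about as large as the naive change at 20 h, and this lower start enters the difference of responses of 0.72. Relative to naive arrays at 0 h, the resistant arrays at 0 h lay at -0.59, -0.58, -0.35 and -0.58. The naive median was -0.21 in replicates 1 and 2 and -0.75 in replicates 3 and 4, and -0.82 after scaling to the 75th percentile. The resistant median at 10 h, 0.01, turned to -0.09 under that scaling. Relative to the mean of naive arrays at 0 h, the family median of single arrays at 10 h in naive cells was 0.12, -0.37, 0.17 and -0.71 in replicates 1 to 4, so arrays of the same group differed by more than the change of the group.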
